A study of Homo sapiens with 10 samples.

How the data were processed

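Small RNA was sequenced from pools of size-exclusion fractions of SW1736 and TPC-1 lysates. Per the labels, lysates were separated on a Superose 6 column, RNA was extracted from the pooled fractions with a serum and plasma miRNA kit, and libraries were made by a ligation-independent method that captures RNAs with a free hydroxyl group at the end (CATS). The authors deposited 1 table per line with raw counts of reads mapped to each of 2656 mature miRNAs and a column of mature miRNA lengths. FastQC, Bowtie2 and Bowtie and the build hg38 are named in the submitters' processing notes, without versions, and the read filters and the miRNA annotation release are not given in the sources used here. The tables list the same miRNAs in the same order. Counts are not normalized. Total counts per library ranged from 405 to 150903, and a floor of 3 reads is used where a count is 0. The method of capture and tailing can favour some ends and base compositions, reads of near-identical family members can be split by the mapping, and amplification without molecular identifiers makes counting intervals too narrow.

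Libraries were grouped by cell line and fraction from the sample titles. Each group has 1 library, and nothing in the labels describes repeated fractionations. The 2 lines therefore served as replicates of a fraction, and p-values measure the spread between these libraries. Counts were filtered with filterByExpr (minimum count 10, groups by fraction), scaled by TMM and fitted over all 10 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with fraction and cell line as terms. All fractions shared 1 estimate of the spread, with 4 residual degrees of freedom, a prior of 20.1 degrees of freedom and a common dispersion of 0.177. Adjusted p-values are Benjamini-Hochberg values over the 108 tested miRNAs, with a threshold of 0.05. The standard error of a log2 change is its size divided by the square root of the quasi-likelihood F statistic. Comparisons made were HMW-RISC against LMW-RISC and each of HMW-RISC, LMW-RISC, MMW-RISC and RISC-poor against Input. The comparisons with Input share its libraries, and no overlap between them was computed. The fit was tried on simulated counts for HMW-RISC against LMW-RISC (108 miRNAs, 24 changed, 20 simulations per fold). It recovered 1% of 2-fold, 29.2% of 4-fold and 83.3% of 16-fold changes, with 16.7%, 3.4% and 4.8% false calls among those made. At 2-fold the false share rests on few calls. Every simulated miRNA had the common dispersion and the same line effect in all pools. These rates therefore need not hold for the real counts.

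The design, the miRNA lists and most other settings were fixed before the data were examined. The 15 lists were the let-7, miR-200, miR-30, miR-29, miR-15/16 and miR-181 families, the miR-17/92 and miR-23/27/24 clusters, miRNAs reported higher or lower in thyroid cancer, miR-34, mesenchymal miRNAs, entries overlapping other noncoding RNAs, miRNAs of other cell types or serum, and the less abundant arm of hairpins with both arms tested. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior of 2), with camera under an estimated correlation, and with fry. Within 1 line no test was run: log2 ratios of TMM-scaled CPM with a prior count of 0.5 were taken for miRNAs with at least 50 reads in both libraries together. Counting intervals of ratios are exact 95% binomial intervals of the split of reads, and per-line folds printed with such intervals use no prior count. A fold against a library or group at 0 reads, written as at least, is a bound at 3 reads. It is not a 95% limit, and the exact counting limit can be lower. A bound over a group adds the reads of both lines, so it can exceed that of either line alone.

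miRNAs were named by a rule fixed in advance: the 12 called miRNAs with the largest change in each direction between HMW-RISC and LMW-RISC and the same sign in both lines, the 10 most abundant, list members with a mean CPM of at least 100, the 5 highest and 5 lowest ratios of each line, and the 5 largest differences between lines in each direction for the ratio and for Input. Other miRNAs are named only because a setting or a left-out library ended or made their call. Other settings were DESeq2 size factors, scaling by total reads, no filter, the DESeq2 1.42.0 Wald test, limma-voom, no cell line term, only the 4 HMW-RISC and LMW-RISC libraries, each of these 4 left out, the 10 most abundant miRNAs left out, and other read minimums (10, 200) and prior counts (5) within lines. Settings added after seeing the data were fits without the RISC-poor libraries, without these and MMW-RISC, and with a linear trend on GC content per library as an offset, and all other settings for the difference between lines.

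Hairpin coordinates and host genes were taken from GENCODE 29 on GRCh38, the build that hg38 names, since the tables hold no coordinates. For mature GC content, the first bases of each tested miRNA, recalled from general knowledge, were located in the GENCODE hairpin of its gene and extended to the deposited length. Of 108 tested miRNAs 107 were placed at 1 position, and miR-574-5p was left out. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).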

Results

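Small RNA libraries were read from size-exclusion fractions of lysates of 2 human thyroid cancer cell lines. SW1736 derives from an anaplastic carcinoma and TPC-1 from a papillary carcinoma. The RNA-induced silencing complex (RISC) is the Argonaute-containing assembly through which a miRNA represses its target transcripts. Per the labels, the high-molecular-weight complexes (HMW-RISC) are the active ones and the low-molecular-weight complexes (LMW-RISC) the inactive ones. The question was how single miRNA species are distributed between them. Values below are shares of the reads of a pool or ratios of scaled reads. The counts do not give the amount of RNA per pool. Higher in a pool therefore means a larger share of its reads, and is not shown to mean more molecules there. The unfractionated lysate (Input), the medium-weight pool (MMW-RISC) and the pool poor in RISC (RISC-poor) served as controls. Each of the 5 pools gave 1 library per line, 10 libraries in all, so the 2 lines are the only replicates of a pool, and values within 1 line have no replicate. Names are those of the deposited tables without the species prefix.

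The libraries differed widely in depth. SW1736 had 150903 miRNA reads in Input, 19719 in HMW-RISC, 5683 in MMW-RISC, 21261 in LMW-RISC and 405 in RISC-poor. TPC-1 had 18090 in Input, 6958 in HMW-RISC, 2000 in MMW-RISC, 14286 in LMW-RISC and 4485 in RISC-poor. Of 2656 listed mature miRNAs, 577 had a read in any library and 108 passed the filter for testing. These 108 held between 94.6% and 98.2% of the reads of each library. The 3-read floor was 0.002% of reads in SW1736 Input, 0.0152% and 0.0431% in the HMW-RISC libraries of SW1736 and TPC-1, and 0.741% in SW1736 RISC-poor. Intervals on shares are exact 95% binomial intervals. Intervals and floors cover counting error only, because reads amplified without molecular identifiers are not independent molecules.

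miR-21-5p, a miRNA raised in many carcinomas, and the let-7 family, repressors of RAS and MYC transcripts in many cell types, dominated opposite pools. miR-21-5p made up 0.751% of SW1736 HMW-RISC reads (95% interval 0.635 to 0.881) and 33.9% of LMW-RISC reads (33.2 to 34.5). In TPC-1 the shares were 0.546% (0.387 to 0.749) and 46.9% (46.1 to 47.7). The 9 let-7 members together made up 59.6% of SW1736 HMW-RISC reads (58.9 to 60.3) against 13.1% in LMW-RISC (12.7 to 13.6), and 49% of TPC-1 HMW-RISC reads (47.9 to 50.2) against 10.9% (10.4 to 11.5). In the Input libraries let-7 held 50.2% (SW1736) and 55.8% (TPC-1), while miR-21-5p held 2.61% and 2.04%. The MMW-RISC libraries held 10.7% and 12.4% miR-21-5p, and the RISC-poor libraries 34.3% and 68.4%. The MIR21 hairpin lies on chromosome 17 from 59841266 to 59841337 (GRCh38, plus strand), in an exon of VMP1.

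**Figure D1:**
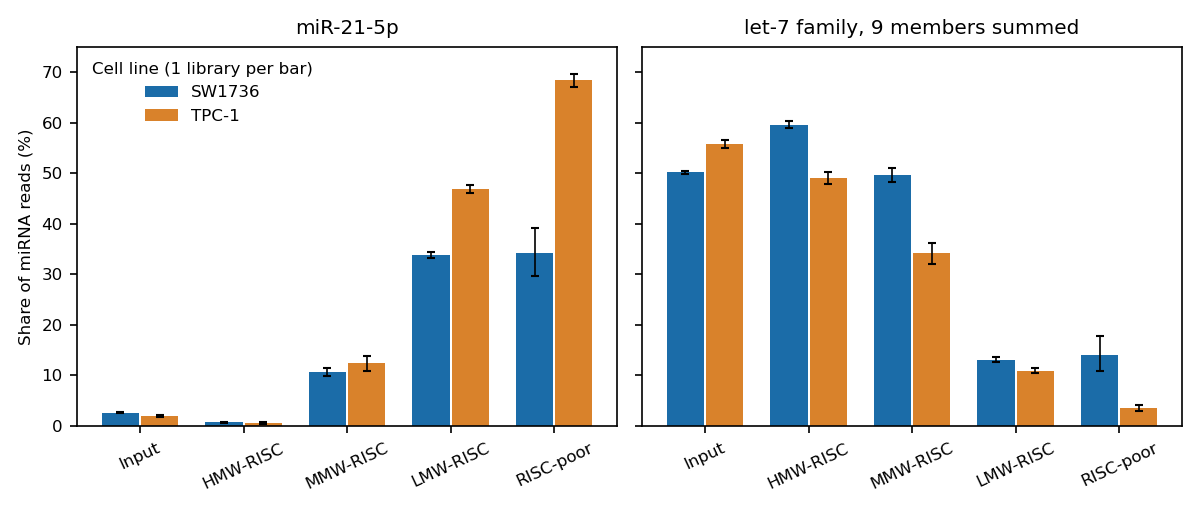
Share of all miRNA reads (%) of miR-21-5p (left) and of the 9 let-7 members summed (right) in each library of SW1736 and TPC-1; each bar is 1 library and error bars are exact 95% binomial intervals. miR-21-5p is at 0.751% and 0.546% in HMW-RISC and at 33.9% and 46.9% in LMW-RISC, and let-7 is at 59.6% and 49% in HMW-RISC and at 13.1% and 10.9% in LMW-RISC.

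Between HMW-RISC and LMW-RISC, 52 of 108 miRNAs differed, 23 higher in HMW-RISC and 29 higher in LMW-RISC (edgeR quasi-likelihood test over both lines with the line as a term, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 55. The balance turned without the 10 most abundant miRNAs (28 higher and 24 lower in HMW-RISC) and without the filter (28 and 23). Of the 52, 51 had the same direction in both lines, which calls from a fit over both lines favour, so this is no separate support. For miR-935 in SW1736 (1 HMW-RISC against 0 LMW-RISC reads) and miR-335-5p in TPC-1 (0 against 1) the direction rests on 1 read. The exception, miR-429, had no read in either SW1736 library and 0 against 39 reads in TPC-1. Log2 changes are given below as HMW-RISC over LMW-RISC with the standard error of the fit. With SW1736 HMW-RISC left out 30 miRNAs were called, without TPC-1 HMW-RISC 30, without TPC-1 LMW-RISC 27 and without SW1736 LMW-RISC 35. The change followed the GC content of the mature miRNA (Spearman rho 0.524 across 107 miRNAs, which are not independent replicates), and with a GC trend removed 31 were called, 19 higher and 12 lower in HMW-RISC. Of these 31, 23 were among the 52, and the others, all higher in HMW-RISC, were let-7f-5p, let-7g-5p, miR-15b-3p, miR-15b-5p, miR-181a-5p, miR-183-5p, miR-224-5p and miR-374b-5p. The calls of miR-107, miR-125a-5p, miR-140-5p, miR-193b-3p, miR-197-3p, miR-26a-5p, miR-30c-5p, miR-335-5p and miR-671-5p were made in none of the 4 fits with a library left out.

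The miRNAs higher in HMW-RISC included both arms of the MIR423 hairpin, an abundant and widely expressed locus in an exon of NSRP1 (chromosome 17, 30117079 to 30117172). miR-423-5p had a log2 change of 4.17 (SE 0.76, adjusted p = 0.000201) and miR-423-3p one of 3.50 (SE 0.84, adjusted p = 0.00162). miR-423-5p had 424 against 30 reads in SW1736 (16.4-fold, counting interval 11.3 to 24.6) and 128 against 10 in TPC-1 (21.1-fold, 11.1 to 45.1). let-7b-5p, from an exon of MIRLET7BHG on chromosome 22 (46113686 to 46113768), was 10.8-fold higher in SW1736 (9.65 to 12) and 10.9-fold higher in TPC-1 (9.31 to 12.8), with an adjusted p of 0.000201. miR-744-5p (log2 change 4.63, SE 0.92), miR-193b-5p (4.50, SE 1.09), miR-574-5p (4.02, SE 0.85), miR-324-3p (3.77, SE 1.08), miR-193a-5p (3.70, SE 0.87) and miR-92b-3p (3.26, SE 0.78) followed. miR-210-3p, a hypoxia-induced miRNA, had a log2 change of 3.23 (SE 0.87), with 11 against 3 reads in SW1736 and 81 against 9 in TPC-1. miR-1307-3p and miR-935 had no LMW-RISC read in either line and were at least 9.96-fold and 5.63-fold higher in HMW-RISC at a floor of 3 reads over the group. Only 1 of the 13 HMW-RISC reads of miR-935 came from SW1736. The calls of miR-324-3p and miR-210-3p were lost when either TPC-1 library was left out, and that of miR-935 when any library but SW1736 HMW-RISC was. With the GC trend removed the calls of miR-324-3p (log2 change 0.34, SE 0.84), miR-210-3p (1.34, SE 0.71), miR-423-3p (1.80, SE 0.66) and miR-92b-3p (1.89, SE 0.66) were lost as the change shrank. Those of miR-1307-3p (SE from 1.64 to 2.34) and miR-935 (SE from 1.91 to 2.25), with no LMW-RISC read, were lost with a larger error, which says little on GC content.

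The miRNAs higher in LMW-RISC were led by miR-19a-3p, an oncogenic member of the miR-17/92 cluster (chromosome 13, 91350891 to 91350972, in an exon of MIR17HG). It had 130 LMW-RISC reads in SW1736 and 163 in TPC-1 and none in either HMW-RISC library. With the reads of both lines added it was at least 75.2-fold higher (edgeR adjusted p = 3.98e-05). Each line alone gave at least 37.3-fold (SW1736) and 32.9-fold (TPC-1). miR-21-5p fell by 5.98 on the log2 scale from LMW-RISC to HMW-RISC (SE 0.76, adjusted p = 4.38e-06). That was 41.9-fold in SW1736 (counting interval 35.6 to 49.6) and 107-fold in TPC-1 (77.7 to 151). miR-27a-3p fell by 5.18 (SE 0.91, adjusted p = 0.00019), with 5 against 507 reads in SW1736 and 9 against 290 in TPC-1. miR-31-3p had a log2 change of -4.44 (SE 0.92) and miR-29b-3p, a repressor of collagen transcripts, one of -4.42 (SE 1.18). miR-135b-5p had 1 against 111 reads in SW1736 (95.6-fold, 16.8 to 3810) and 0 against 64 in TPC-1 (at least 12.9-fold). miR-5100 had 1 against 95 reads in SW1736 and 0 against 23 in TPC-1, and miR-30b-5p 0 against 31 and 1 against 14. With no HMW-RISC read in either line, miR-200a-3p was at least 16.2-fold, miR-186-5p at least 11.5-fold and miR-374a-5p at least 11.3-fold higher in LMW-RISC. miR-186-5p and miR-374a-5p did not pass the filter with SW1736 HMW-RISC, SW1736 LMW-RISC or TPC-1 LMW-RISC left out, and the miR-30b-5p call was kept only without TPC-1 HMW-RISC. With the GC trend removed the calls of miR-29b-3p (-2.14, SE 1.58) and miR-30b-5p (-3.16, SE 1.48) were lost with a smaller change and a larger error. Those of miR-200a-3p (SE from 1.99 to 3.33) and miR-374a-5p (SE from 1.74 to 2.92), with no HMW-RISC read, were lost with a larger error, which says little on GC content.

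**Figure D2:**
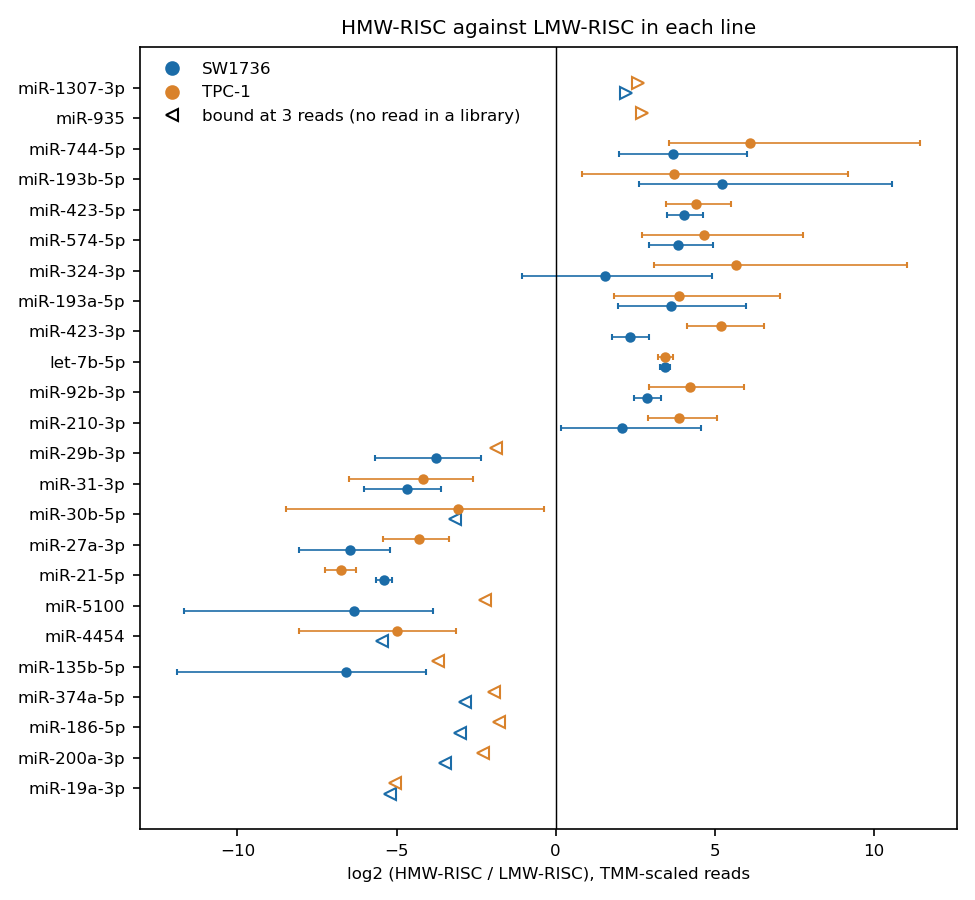
Log2 ratio of TMM-scaled reads, HMW-RISC over LMW-RISC, in SW1736 and TPC-1 for the 12 called miRNAs with the largest fitted change in each direction and the same sign in both lines. Points have 95% counting intervals; open triangles are bounds at 3 reads where a library had no read (miR-935 in SW1736, with 1 and 0 reads, is not drawn). All drawn values of the upper 12 lie above 0 and all of the lower 12 below 0, and the intervals of let-7b-5p and miR-21-5p are the narrowest of each set.

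By miRNA list, 5 of the 9 let-7 members were higher in HMW-RISC and none was lower, also when adjusted over the list alone. let-7e-5p had a log2 change of 2.79 (SE 0.67), let-7c-5p 2.67 (SE 0.60), let-7a-5p 2.51 (SE 0.59) and let-7d-5p 2.38 (SE 0.67), beside let-7b-5p. The other members did not pass: let-7g-5p at 0.58 (SE 0.67), let-7i-5p at -0.09 (SE 0.67), let-7f-5p at -0.11 (SE 0.63) and miR-98-5p at -1.09 (SE 0.90). With the GC trend removed let-7g-5p (3.21, SE 0.78) and let-7f-5p (3.195, SE 0.59) were called as well. Of the let-7 calls, let-7b-5p alone was kept whichever HMW-RISC or LMW-RISC library was left out. Of 7 tested members of the miR-17/92 clusters, proliferation-linked polycistrons, miR-17-5p (-2.15, SE 0.81), miR-20a-5p (-3.54, SE 0.87), miR-19a-3p and miR-19b-3p (-4.12, SE 0.86) were lower in HMW-RISC and miR-92a-3p was higher (2.05, SE 0.67). All 5 have a hairpin in an exon of MIR17HG. With the GC trend removed miR-19a-3p alone of the 5 stayed called (miR-17-5p -1.36, SE 0.86; miR-20a-5p -1.43, SE 0.69; miR-19b-3p -1.86, SE 1.09; miR-92a-3p 1.83, SE 0.74). The miR-92a-3p call was kept in 1 of the 4 fits with a library left out and the miR-17-5p and miR-20a-5p calls in 2, and the miR-17-5p call was also lost with total reads and without the filter. miR-93-5p and miR-25-3p of the sister cluster were not called, with log2 changes of -0.61 (SE 0.88) and 1.22 (SE 0.68). The counts were the same when adjusted over the list alone. All 3 tested members of the miR-30 family were lower in HMW-RISC, by either adjustment: miR-30b-5p at -4.87 (SE 1.29), miR-30a-5p at -4.01 (SE 0.88) and miR-30c-5p at -1.79 (SE 0.67). The miR-30c-5p call was lost whichever library was left out, with total reads and with the GC trend removed (-0.33, SE 0.62). Without TPC-1 HMW-RISC the miR-30a-5p call was lost, and that of miR-30b-5p was kept only without this library. Of the miR-200 family, which holds cells in an epithelial state, miR-200a-3p and miR-429 were lower in HMW-RISC and miR-200b-3p (-1.62, SE 0.78) was not called, while all 3 passed when adjusted over the list alone. The median of the 3 fitted values was -7.22, and -3.32 with the members at 0 reads set to their bounds. The miR-429 call rests on TPC-1 reads only, was lost without TPC-1 HMW-RISC, did not pass the filter without TPC-1 LMW-RISC, and was lost with the GC trend removed (SE from 2.13 to 3.10).

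Of 5 members of the miR-23/27/24 clusters, miR-27a-3p and miR-27b-3p (-3.13, SE 0.80; kept in 2 of the 4 fits with a library left out) were lower in HMW-RISC, also when adjusted over the list alone, and miR-23a-3p (-0.51, SE 0.57), miR-23b-3p (-0.16, SE 0.61) and miR-24-3p (-1.16, SE 0.64) were not called. miR-16-5p was lower in HMW-RISC (-3.23, SE 0.83) and its relative miR-15b-5p was not called (1.17, SE 0.74). With the GC trend removed this turned, with miR-16-5p not called (-2.08, SE 0.79) and miR-15b-5p called (2.96, SE 0.65), and the miR-16-5p call was also lost without SW1736 HMW-RISC. In the miR-29 family miR-29b-3p was lower and miR-29a-3p not called (-0.52, SE 0.72). The miR-29b-3p call was lost without TPC-1 HMW-RISC and with the GC trend removed (-2.14, SE 1.58). Neither tested miR-181 member was called, with log2 changes of 1.26 (SE 0.74) for miR-181a-5p and 0.33 (SE 0.78) for miR-181b-5p, although miR-181a-5p was called with the GC trend removed (2.06, SE 0.68). Of 6 tested miRNAs from the list reported higher in thyroid cancer, miR-21-5p was lower in HMW-RISC and 5 were not called, among them miR-221-3p at -1.15 (SE 0.69) and miR-31-5p at 0.52 (SE 0.84). Of 5 from the list reported lower, miR-30a-5p and miR-26a-5p (-3.07, SE 0.96) were lower in HMW-RISC and 3 were not called. The miR-26a-5p call was lost whichever library was left out and with the GC trend removed (-1.35, SE 1.09). The mesenchymal list had 1 tested member, miR-100-5p, lower in HMW-RISC (-3.37, SE 0.85), a call lost without TPC-1 HMW-RISC. Of 14 minor arms, 3 were higher in HMW-RISC (miR-193b-5p, miR-423-3p, miR-574-5p), 3 lower (miR-31-3p, miR-30a-5p, miR-140-5p) and 8 not called. The miR-140-5p call was lost whichever library was left out and with the GC trend removed (-1.56, SE 0.64), which also ended that of miR-423-3p. The counts of these lists were the same when adjusted over the list alone. miR-4454, the 1 tested entry of those overlapping other noncoding RNAs, was lower in HMW-RISC, with 0 against 153 reads in SW1736 and 2 against 106 in TPC-1. No miR-34 member was tested. Markers of other cell types or serum were mostly miR-486-5p, a miRNA of red blood cells and muscle, with 39 reads in SW1736 HMW-RISC and 10 in LMW-RISC. These markers made up 0.213% of SW1736 HMW-RISC reads (0.154 to 0.288) and 0.0753% of LMW-RISC reads (0.043 to 0.122), and had 0 and 1 read in the same TPC-1 libraries. miR-486-5p was not called (2.14, SE 1.07).

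As sets, none of the 8 lists with at least 3 tested members passed the camera test against the other miRNAs (preset correlation, adjusted p under 0.05). At an unadjusted p under 0.05 there were 2, the let-7 family (adjusted p = 0.0692) and the miR-30 family (adjusted p = 0.17). With an estimated correlation there was none at either level (adjusted p = 0.351 for both lists). The fry test, which asks whether the members of a list move one way on balance and makes no comparison with other miRNAs, passed for 5 lists: let-7 upward in HMW-RISC (adjusted p = 0.0272) and the miR-17/92 (adjusted p = 0.0272), miR-200 (0.0315), miR-30 (0.000292) and miR-23/27/24 lists (0.0198) downward. Members of let-7 and of the pairs miR-19a/b, miR-23a/b, miR-27a/b differ at few positions, and the split of reads between them is uncertain.

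Within each line, the fractions were compared without a test. In SW1736, 44 of 61 miRNAs with at least 50 reads in both fractions together were at least 2-fold apart, 16 higher in HMW-RISC and 28 higher in LMW-RISC. In TPC-1 this held for 31 of 47, 15 and 16. The highest ratios in SW1736 were those of miR-423-5p, miR-574-5p, let-7e-5p, let-7b-5p and let-7c-5p. In TPC-1 they were those of miR-423-3p, miR-423-5p, miR-92b-3p, miR-210-3p and let-7b-5p. Over the 42 miRNAs with enough reads in both lines the log2 ratios correlated across miRNAs, which are not independent replicates, with Pearson's r of 0.904 and Spearman's rho of 0.88. Signs were equal for 36 and opposite for 6. Without the 3 miRNAs that had a library at 0 reads r was 0.88, and without the let-7 family 0.911.

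The lines also differed. For 23 of the 42 miRNAs the ratios differed by more than 2 counting standard errors, with no replicate to test it. let-7f-5p was 2.01-fold higher in HMW-RISC in SW1736 (counting interval 1.81 to 2.24) and 2.19-fold higher in LMW-RISC in TPC-1 (1.72 to 2.81). miR-93-5p was 5.85-fold higher in LMW-RISC in SW1736 (3.98 to 8.90) and 1.70-fold higher in HMW-RISC in TPC-1 (1.20 to 2.41). miR-125b-5p was 1.93-fold higher in LMW-RISC in SW1736 (1.76 to 2.11) and 2.27-fold higher in HMW-RISC in TPC-1 (1.80 to 2.88). With the same direction in both lines, the log2 ratio of miR-423-3p was 2.32 in SW1736 and 5.16 in TPC-1, that of miR-27a-3p -6.34 and -4.26 and that of let-7e-5p 3.43 and 2.15. The differences of miR-4454, miR-135b-5p and miR-146a-5p were within 2 counting standard errors.

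**Figure D3:**
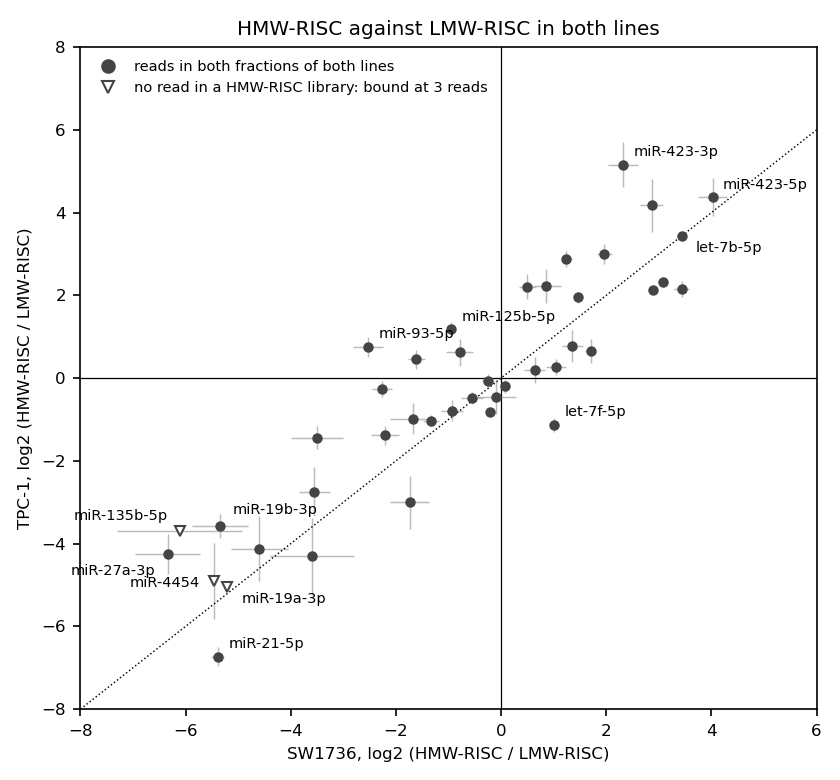
Log2 ratio of HMW-RISC over LMW-RISC (TMM-scaled reads) in SW1736 (x axis) and TPC-1 (y axis) for the 42 miRNAs with at least 50 reads in each line; bars are 1 counting standard error, open triangles mark bounds at 3 reads, and the dotted line marks equal ratios. Most points lie in the lower left and upper right, 36 of 42 with equal signs, and let-7f-5p, miR-93-5p and miR-125b-5p are among the 6 with opposite signs.

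The control pools were compared with Input by the same fit. Between HMW-RISC and Input, edgeR called 0 of 108 miRNAs, with 13 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 2, in both cases miR-181a-5p (higher in HMW-RISC) and miR-29b-1-5p (lower). In the edgeR fit these had log2 changes of 2.40 (SE 0.75, adjusted p = 0.142) and -3.67 (SE 0.95, adjusted p = 0.078). The rank correlation of the tested miRNAs between HMW-RISC and Input was 0.89 in SW1736 and 0.8 in TPC-1. The values for LMW-RISC and Input were 0.53 and 0.41.

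Between LMW-RISC and Input, 45 miRNAs differed, 26 higher and 19 lower in LMW-RISC, 44 of them with the same direction in both lines, miR-429 being the exception. miR-21-5p rose by a log2 change of 4.18 (SE 0.69, adjusted p = 0.000113), miR-19b-3p by 6.77 (SE 0.96, adjusted p = 1.51e-05) and miR-27a-3p by 4.91 (SE 0.85, adjusted p = 0.000157). miR-19a-3p had 293 reads in the LMW-RISC libraries and 2 in the Input libraries. Among the lower miRNAs, let-7b-5p had a log2 change of -2.86 (SE 0.61), let-7a-5p -2.63 (SE 0.59), miR-423-5p -3.11 (SE 0.73) and miR-574-5p -3.61 (SE 0.84). The median log2 change of all tested miRNAs was -0.072 with TMM and -0.191 with DESeq2 size factors. Without the line as a term 25 were called.

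Between MMW-RISC and Input, edgeR called 0 miRNAs, with 15 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. miR-21-5p had a log2 change of 2.02 (SE 0.63, adjusted p = 0.246). It was the 1 miRNA called when libraries were scaled by total reads. The median of all tested miRNAs moved from -0.18 with TMM to 0.062 with that scaling. Of the 52 miRNAs called between HMW-RISC and LMW-RISC, the MMW-RISC level lay between the 2 for 36 in SW1736 and 26 in TPC-1, and was nearer to HMW-RISC for 37 and 44. The MMW-RISC libraries had only 5683 and 2000 reads, and miRNAs at no read in both pools count as nearer to HMW-RISC. In TPC-1 these include miR-135b-5p, miR-200a-3p, miR-374a-5p and miR-429. The counts therefore do not show that MMW-RISC resembles HMW-RISC.

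Between RISC-poor and Input, 24 miRNAs differed, 10 higher and 14 lower in RISC-poor, with 22 in the same direction in both lines. With total reads as the scaling the split was 7 and 17, and with DESeq2 size factors 10 and 20, as the median log2 change of all miRNAs moved from -0.298 to -0.65 and -0.7. limma-voom turned the balance, with 12 higher and 10 lower and a median of 0.196. miR-21-5p was higher in RISC-poor (4.66, SE 0.72, adjusted p = 5.78e-05), as was miR-19b-3p (6.41, SE 0.98, adjusted p = 5.78e-05). let-7a-5p (-3.89, SE 0.66), let-7c-5p (-3.53, SE 0.67), let-7b-5p (-3.20, SE 0.65), let-7d-5p (-2.67, SE 0.76), let-7e-5p (-2.65, SE 0.75) and let-7f-5p (-2.31, SE 0.70) were lower. miR-423-3p had no read in either RISC-poor library against 905 in the Input libraries, at least 6.24-fold lower. With 405 reads, the SW1736 RISC-poor library had 59 miRNAs with a read and only 6 with 10 or more. Without the line as a term 12 were called.

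The Input libraries of the lines, 1 each, were compared without a test. Of 107 miRNAs with at least 50 reads, 15 were at least 4-fold apart, 13 higher in SW1736 and 2 higher in TPC-1. SW1736 Input had 150903 reads and TPC-1 Input 18090, so a miRNA read only in SW1736 passed the minimum at a lower share. The balance of 13 to 2 therefore depends on depth and cannot be read as a difference between the lines. Of the 13, 11 remained past 4-fold with TPC-1 counts of 0 set to 3 reads. Low TPC-1 counts above 0 were kept as read, and their counting intervals can start under 4-fold. Both arms of MIR424, whose 5p arm is a relative of miR-16, had Input reads only in SW1736. miR-424-3p had 247 against 0 reads (at least 10.3-fold higher at 3 reads, with the counting interval starting at log2 3.05). miR-424-5p had 68 against 0 (at least 2.83-fold, interval from log2 1.16). miR-486-5p had 175 against 0 (at least 7.26-fold), miR-1269b 52 against 0 (at least 2.16-fold) and miR-335-5p 206 against 1 (log2 ratio 4.23, counting interval 2.19 to 9.99). The 2 higher in TPC-1 were miR-331-3p (63 against 41 reads, 5.03-fold after scaling) and miR-210-3p (61 against 34, 4.32-fold). miR-29b-1-5p was 3.48-fold higher in TPC-1.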

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

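Both tests in this part were chosen after the result was seen. let-7f-5p moved in opposite directions in the lines. Its HMW-RISC over LMW-RISC ratio differed by 2.13 on the log2 scale (1.01 in SW1736, -1.13 in TPC-1, counting SE 0.19), and with 1 library each the difference was not tested. let-7f-5p differs from let-7a-5p by 1 base (G12A, let-7a base first, positions from 1 at the mature 5′ end). Reads of let-7a counted as let-7f cannot be told apart as a contributor: the let-7f to let-7a read ratio differed between the pools (odds ratio 0.272 in SW1736 and 0.105 in TPC-1), but let-7f reads of its own beside a constant shared fraction would also give unequal ratios, so this decides nothing. The scaling cannot be told apart as a contributor: the signs held with TMM, total reads and DESeq2 size factors, but with total reads the log2 ratios had sizes of 0.88 (toward HMW-RISC, SW1736) and 0.81 (toward LMW-RISC, TPC-1), both under 2-fold. A difference between the lines themselves stays open and untested.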

How the results depend on the processing

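Fits without the RISC-poor or MMW-RISC libraries, the GC trend and all alternatives for the difference between lines were chosen after seeing the data. Between HMW-RISC and LMW-RISC, the 52 calls became 45 to 59 under the other scalings, tests, filters and library sets, 31 without the line term, 31 with the GC trend removed and 27 to 35 with 1 library left out. The lowest was without TPC-1 LMW-RISC (27), followed by SW1736 HMW-RISC (30), TPC-1 HMW-RISC (30) and SW1736 LMW-RISC (35). Of the 52, 17 were kept in all 4 left-out fits (8 higher and 9 lower in HMW-RISC) and 9 in none. A lone library is then assumed to vary like the other groups. None of the 52 changed sign except miR-335-5p under the GC trend (0.016, adjusted p = 0.979). That setting also turned let-7f-5p to 3.195 (adjusted p = 0.00359), miR-374b-5p to 2.48 (adjusted p = 0.0123) and miR-15b-3p to 2.03 (adjusted p = 0.042), the construction of the setting raising AT-rich miRNAs in HMW-RISC.

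Between HMW-RISC and Input, where edgeR with TMM called 0, DESeq2 size factors gave 3 (miR-181a-5p, miR-29b-1-5p, miR-4286), total reads 1 (miR-21-5p), no filter 2 (miR-29b-1-5p, miR-4286), the DESeq2 test 2, limma-voom 2, and the fit without RISC-poor 5 (let-7b-3p, miR-181a-5p, miR-21-5p, miR-29b-1-5p, miR-4286). Between MMW-RISC and Input, total reads and the fit without RISC-poor each gave 1 (miR-21-5p). Without the line term LMW-RISC against Input gave 25 and RISC-poor against Input 12. The causes were not tested. The camera test of lists passed 0 under every alternative run.

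Within lines, a minimum of 10 or 200 reads gave 101 or 24 miRNAs at least 2-fold apart in SW1736, 79 or 14 in TPC-1, and 43 or 3 at least 4-fold apart between Input libraries, since more or fewer miRNAs enter. A prior count of 5 gave 4 for Input. let-7f-5p was the 1 miRNA at least 2-fold apart in opposite directions, against 2 with total reads and 5 with a minimum of 10 reads. A count of 3 reads was 0.741% of SW1736 RISC-poor, 0.0669% of TPC-1 RISC-poor and 0.15% of TPC-1 MMW-RISC. In simulated data 29.2% of 4-fold changes between HMW-RISC and LMW-RISC were found, so a miRNA not called is not shown to be evenly distributed.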

Other observations

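Arms and neighbours of one transcript had different values between HMW-RISC and LMW-RISC, and none of these differences was tested. miR-31-3p was lower in HMW-RISC (log2 change -4.44, SE 0.92) while miR-31-5p from the same hairpin was at 0.52 (SE 0.84), with log2 ratios of -1.11 in SW1736 and 2.84 in TPC-1. miR-30a-5p was lower (-4.01, SE 0.88) and miR-30a-3p was at -0.52 (SE 0.64). Both arms of MIR423 were higher in HMW-RISC. Within MIR17HG, miR-92a-3p (2.05, SE 0.67) was higher in HMW-RISC and miR-19b-3p (-4.12, SE 0.86) lower, although miR-92a-3p and miR-19b-3p each have a second hairpin on chromosome X. miR-27a-3p (-5.18, SE 0.91) and miR-23a-3p (-0.51, SE 0.57) share an exon of AC020916.1 on chromosome 19.

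The tests of base composition and of abundant miRNAs were chosen after the result was seen. The log2 change between HMW-RISC and LMW-RISC followed mature GC content, with a rho of 0.524 (0.412 in SW1736 and 0.564 in TPC-1). The permutation p was 1e-04, the smallest the permutations can give. It comes from shuffling miRNAs, which are not independent replicates, and does not measure the spread between libraries or lines. Median GC content was 59.09% for miRNAs called higher in HMW-RISC and 40.91% for those higher in LMW-RISC. Without the let-7 family rho was 0.655. Of 46 testable calls, 91.3% were kept without the 10 most abundant miRNAs, so most of these calls did not need those 10 in the fit. Both fits were scaled by TMM, which already limits the pull of a few abundant miRNAs. The calls of the removed miRNAs could not be tested. Whether abundant miRNAs took the reads therefore cannot be decided by this. Unequal depth is argued against, for calls that stayed testable, by 84.4% of 45 kept when the 4 libraries were thinned to 6958 reads. The thinning was a single random draw that left the other libraries of the fit as they were. For the rest of the 52 calls, which then fell below the filter, it cannot decide. A linear GC trend, at 29.2% of the variance, is not the whole cause. With it removed 45.1% of 51 testable calls stayed, among them let-7b-5p, miR-423-5p, miR-21-5p, miR-27a-3p and miR-19a-3p. That share was partly fixed in advance, since the setting enlarges calls that run against the trend. let-7b-5p went from 3.435 to 4.585, let-7a-5p from 2.51 to 5.05 and miR-4454 from -7.06 to -8.84. Of calls along the trend, miR-21-5p shrank from -5.98 to -3.475 and miR-423-5p from 4.17 to 3.69, and both stayed. The 28 calls lost went from a median size of 3.23 (median SE 0.95) to 1.56 (SE 0.85). This does not hold for each: miR-1307-3p, miR-935, miR-200a-3p, miR-374a-5p and miR-429, each with a pool at 0 reads, and miR-92a-3p (2.05, SE 0.67, to 1.83, SE 0.74) and miR-22-3p (-4.39, SE 1.02, to -3.34, SE 1.19) kept most of the fitted change and had a larger error. What stays open is whether the trend may come from capture or recovery that differed between pools by base composition or from sorting of the miRNAs themselves, which these libraries cannot separate.

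Both tests of the next pattern were chosen before its result was seen, while the bootstrap ranges of rho and the rho within the LMW-RISC set were added after. If Input were a mix of the 4 pools, the fitted weights were 86.6% HMW-RISC, 7.2% MMW-RISC and 6.2% LMW-RISC in SW1736 (LMW-RISC range over 200 resamples 4.2 to 8.2) and 82.3%, 17.7% and 0% in TPC-1. The 29 miRNAs higher in LMW-RISC had a median mixed share above the observed Input share by 1.35-fold in SW1736 (1.24 to 1.74) and 1.24-fold in TPC-1 (0.73 to 1.40), and the 23 higher in HMW-RISC by 1.46-fold and 1.49-fold, so the shortfall was not special to the LMW-RISC set. It is also partly built in, since 0.5 reads were added to each miRNA in the 4 pools before the fit. The same was added to Input only afterwards, when its observed share was formed. miR-486-5p, with no read in any TPC-1 library, had a mixed share of 0.0105% there against 0.00282% observed. With an LMW-RISC weight of 0%, the TPC-1 shortfall says nothing on LMW-RISC content. Base composition cannot be told apart as a contributor. Over all miRNAs, rho between GC content and observed over mixed share was -0.013 in SW1736 (bootstrap range over miRNAs -0.23 to 0.197). In TPC-1 it was -0.304 (-0.493 to -0.109). Both ranges lay under the bound of 0.2, in SW1736 by a narrow margin, but the TPC-1 range excluded 0, a trend in the other direction. Within the 29 miRNAs rho was 0.184 (-0.268 to 0.601) and 0.255 (-0.16 to 0.608), too wide to decide for them alone. Counting error cannot be told apart because the TPC-1 range spans 1. A different recovery of the pools was not tested.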
